A study of Mus musculus with 10 samples.

How the data were processed

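Small RNA was sequenced from small extracellular vesicles (sEV) of C57BL/6J mice. The vesicles came from brown adipose tissue (BAT) or from plasma, and the 10 libraries fall into 4 groups named by their titles: Sed BAT (3 libraries), Exe BAT (3), Sed plasma (2) and Exe plasma (2). The series describes a comparison before and after exercise, so Sed is read here as the group without training. The labels give the same schedule of 90 min sessions, 2 per day for 4 weeks, for every sample, Sed included. Vesicle RNA was extracted with Trizol and made into Illumina libraries, per the labels' protocols. Nothing in the labels says that the replicates are separate animals, so p-values measure only the spread between these libraries, which may be technical.

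The authors deposited 1 table per vesicle source, with a read count per mature miRNA and library, per the file headers. Bowtie 0.12.2 and the genome builds mm8 and mm9 are named in the submitters' processing notes, with no role given. The counting program, the miRBase release, adapter trimming and filters are not given in the sources used here. The BAT table, as deposited, also holds values found to be RPM (reads scaled to the total of the library): each equals the read count divided by 1 total per library, within 0.01, and the totals so implied lie between 18.9 and 21.2 in units of 1000000 reads. The plasma table, as deposited, holds a further whole number beside each read count, never larger than it, whose making is not stated and which may count distinct reads or molecules. These second plasma values were used only as an alternative. For BAT 679 miRNAs are listed. Of 436 listed for plasma, 53 have no read in any library, and 394 are in both. The let-7a-1-3p and let-7c-2-3p values are identical in every library, as are those of miR-199a-3p and miR-199b-3p and those of miR-486a-5p and miR-486b-5p. Their sequences are shared, so the reads cannot be assigned to either member, and they are reported as uncertain.

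The read counts were analysed as deposited, with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each comparison of Exe with Sed used edgeR's quasi-likelihood test with TMM scaling, the filterByExpr filter, robust dispersions and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Adjusted p-values come from that test unless another tool is named. The standard error (SE) of a log2 fold change was taken as its size over the square root of the F statistic. The difference of exercise effects between sources, and BAT against plasma in Sed libraries, were tested in a joint edgeR fit of the 4 groups over shared miRNAs. Source, table and any sequencing batch cannot be told apart in that fit. CPM values are counts scaled to 1000000 reads on the TMM scale. Fold changes against a group at 0 reads are lower bounds set against a floor of 3 counts over the group. With 1 to 3 reads the ratio is given with an exact 95% counting interval. Such intervals and floors cover counting error only, since PCR copies of a molecule are not independent and no label speaks of molecular identifiers. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for exact permutation tests and plots.

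The tests, the alternatives, the lists and the rule for named miRNAs were fixed before the data were examined. The rule takes the miRNAs followed up in heart cells by the study, the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap and a mean of at least 10 counts, the 10 most abundant, and from each list up to 4 members of smallest p and every member past the threshold. If fewer than 5 pass, the 10 smallest unadjusted p are given as values. For BAT against plasma the 10 largest in each direction are named, and for the difference of effects the 10 smallest p. The 19 lists are study candidates, brown fat promoting, brown fat restraining, adipose vesicle, adipocyte, muscle, liver, red cell, blood leukocyte, endothelial and platelet, fibroblast and stromal, neural, epithelial, the let-7 and miR-98 family, the miR-30 family, the miR-29 family, the miR-17-92 clusters, the Dlk1-Dio3 cluster and exercise in blood. The study candidates were chosen by the study on these samples. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry (limma), in one direction and in mixed directions.

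The alternatives were DESeq2, upper-quartile factors, library size alone, no filter, a mean of at least 50 counts, limma-voom, the replicate number as a block, leaving out the 3 most abundant miRNAs and leaving out each library in turn. Chosen after seeing the data were the library totals implied by RPM, identical miRNAs counted once, the second plasma values and limma-voom with a spread for each source. Names of miRNA genes, neighbours within 10 kb and host genes came from GENCODE M21 (GRCm38), which held a gene of the same name for 683 of 721 miRNAs, and exactly 1 for 636. As its build differs from the builds in the processing notes, no coordinates are given.

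The fits were tested on simulated data, in 20 runs with 40 miRNAs changed in each, drawn from the real means, library sizes and dispersions. Of BAT miRNAs changed 2-fold, 4-fold and 8-fold, 39.6%, 91.9% and 98.8% were recovered among a mean of 200.5 tested, and 5.75% of calls were false. With none changed, 0.35 miRNAs were called per run. With the plasma libraries' own spread, 0% of 2-fold and 0.769% of 8-fold changes were recovered among a mean of 200.6 tested, against 15.4% and 95% when the plasma libraries were given the BAT spread. The plasma test therefore had almost no power at the spread these 4 libraries show. The joint fit holds 1 dispersion per miRNA for both sources. Simulated with each source's own spread and no difference of effects, it called 4.1 miRNAs per run, and limma-voom with a spread for each source called 0.4. With the BAT spread in every library it called 0.2. With differences present and the own spread of each source, 60% of the calls of the joint fit were false and 7.31% of 8-fold differences were recovered, against 42.9% and 1.92% with a spread for each source. These shares rest on few calls, with 2.25 and 0.3 false ones per run. For BAT against plasma with no difference, the miRNAs called per run were 1.85 with the joint fit, 0.1 with a spread for each source and 0.1 with the BAT spread. A list shifted 2-fold passed in 20 of 20 simulated BAT runs, and another list passed in 1. The simulated miRNAs were drawn independently of each other. These runs therefore do not cover correlation between list members, estimated at 0.25 for the Dlk1-Dio3 cluster in the real BAT libraries.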

Results

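Vesicle miRNAs were counted in 6 BAT libraries and 4 plasma libraries from mice with training (Exe) or without it (Sed). The BAT libraries held 169345, 104064 and 116084 miRNA reads in Sed and 116584, 158795 and 172279 in Exe. The plasma libraries were deeper, with 1341678 and 1798169 miRNA reads in Sed and 1209116 and 1766070 in Exe. Between 420 and 470 miRNAs had a read in each BAT library and between 197 and 296 in each plasma library. Reads of miRNAs made up 0.629% ± 0.178 of the BAT Sed libraries and 0.78% ± 0.148 of the BAT Exe libraries (SD, n = 3 each, exact permutation p = 0.3, two-sided, where 0.1 is the smallest possible).

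The most abundant BAT vesicle miRNA was miR-378a-3p, which lies within the gene of the coactivator PGC-1β. It took 16.7% and 21.4% of reads in Sed replicates 1 and 3 and 27.1%, 21.3% and 20.7% in the Exe libraries. Sed replicate 2 stood apart, with miR-126a-3p in first place at 10.5% (exact 95% counting interval 10.3 to 10.7) and 3804 reads of miR-378a-3p, against 24801 to 35733 in the other BAT libraries. In plasma, the red cell miRNA miR-451a took 69.8% and 52.8% of the Sed reads, while let-7c-5p came first in Exe, with 17.0% and 14.3%.

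The first comparison asked what exercise did to the miRNAs of BAT vesicles. The deepest fall was that of miR-136-5p, from the imprinted Dlk1-Dio3 cluster, whose products are tied to growth and development. It fell from 648 ± 166 to 84.4 ± 20.5 CPM (SD, n = 3 each), a log2 fold change of -2.93 ± 0.32 (SE, adjusted p = 0.000838), and miR-379-5p of the same cluster from 951 ± 62.7 to 241 ± 52.3 CPM (-1.97 ± 0.25, adjusted p = 0.0017). Falls also took in miR-96-5p, a miRNA of sensory and epithelial cells (-1.94 ± 0.30, adjusted p = 0.00471), the muscle miRNAs miR-1b-5p (-1.59 ± 0.25) and miR-1a-3p (-1.47 ± 0.30), and the growth-restraining let-7c-5p (-1.61 ± 0.32) and let-7b-5p (-1.52 ± 0.26). Further large falls were those of miR-1949 (-2.005), miR-24-1-5p (-1.72), miR-411-5p (-1.65) and miR-1291 (-1.61).

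Among miRNAs with a mean of at least 10 counts and groups that did not overlap, rises were led by miR-1249-3p, with 9 reads over the Sed libraries and 69 over the Exe libraries (2.76 ± 0.63, adjusted p = 0.0151). Next came miR-26a-2-3p (2.01 ± 0.43), the let-7a-1-3p and let-7c-2-3p pair that shares its reads (2.01 ± 0.39), miR-6538 (1.95), miR-30c-1-3p (1.94), miR-350-3p (1.75), miR-203b-5p (1.69), miR-193a-5p (1.43) and miR-139-5p (1.31). Together, 45 of 199 tested miRNAs passed the threshold in edgeR's quasi-likelihood test, 19 higher and 26 lower in Exe. The calls of miR-136-5p, miR-379-5p, miR-96-5p, miR-1b-5p, let-7b-5p, miR-139-5p and miR-328-3p held under every alternative in which they were tested.

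The count depended on single libraries and on scaling. It was 22, 28 and 16 without Exe replicates 1, 2 and 3, and 56 without Sed replicate 2, the library that stood apart. Upper-quartile factors, which moved the median log2 fold change by 0.14, gave 26 higher and 20 lower, and the library totals implied by RPM, which moved it by 0.22, gave 22 higher and 13 lower. Library size alone moved the median by -0.13.

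**Figure D1:**
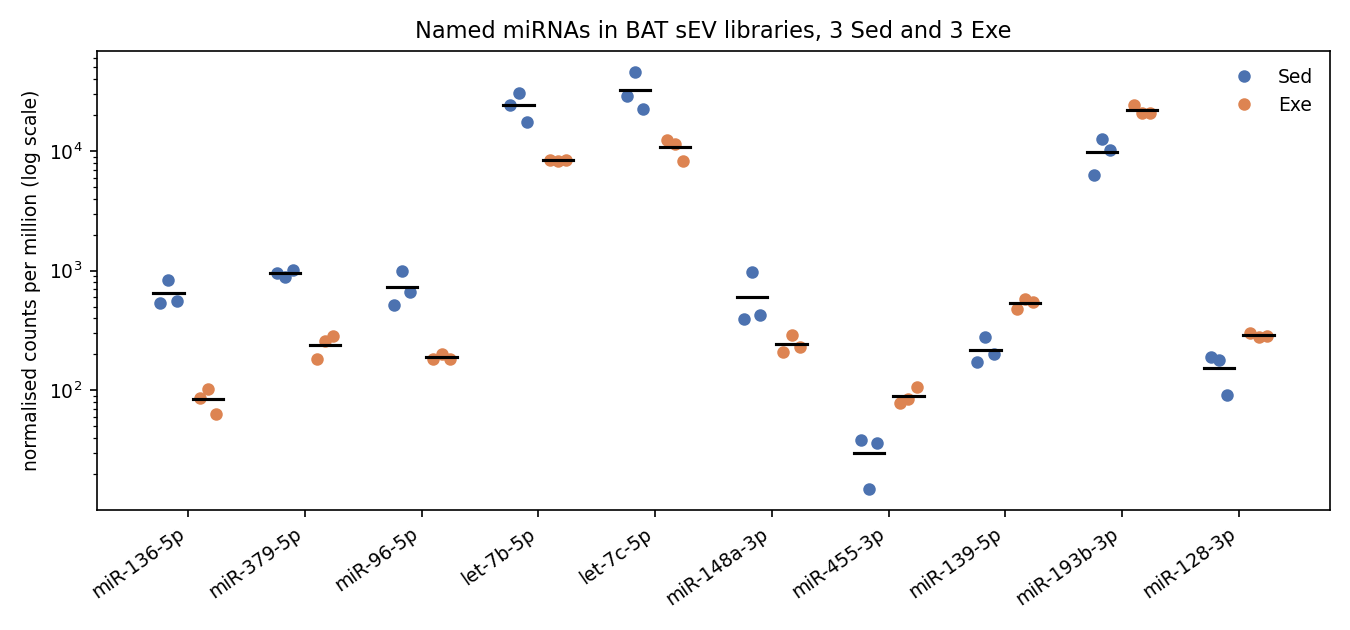
Normalised CPM on a log axis of 10 miRNAs in the 3 Sed and 3 Exe BAT vesicle libraries, each point a library and each line a group mean. The Exe points lie below the Sed points for miR-136-5p, miR-379-5p, miR-96-5p, let-7b-5p, let-7c-5p and miR-148a-3p and above them for the others, of which miR-128-3p did not pass the threshold (adjusted p = 0.0711).

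By list, 7 of the 11 tested Dlk1-Dio3 miRNAs fell and none rose, and 7 fell when adjusted over the list alone. Beside miR-136-5p, miR-379-5p and miR-411-5p these were miR-376a-3p (-2.001, with overlapping groups), miR-369-3p (-1.71), miR-381-3p (-1.001) and miR-154-5p (-0.84), and the list's median was -1.001, or -1.72 to -0.79 with 1 library left out. The falls past the threshold were 4 with DESeq2 and 4 with the library totals implied by RPM. All 11 values were below 0, except that 1 lay above 0 with upper-quartile factors and 2 with the library totals implied by RPM. The Dlk1-Dio3 cluster was the 1 list of 19 past the threshold with camera (adjusted p = 0.00121), and it did not pass with an estimated correlation (p = 0.0804, adjusted p = 0.763 with an estimated correlation) nor with fry for a change in one direction, while 11 lists passed fry for changes in mixed directions. The number of lists past the threshold was 2 without Exe replicate 1, 2 without Sed replicate 2 and 3 without Sed replicate 3.

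In the let-7 and miR-98 family, which represses growth genes, 6 of 12 tested members fell and 2 rose (7 and 3 adjusted over the list alone), with a camera adjusted p of 0.41. The falls were all 5p arms: let-7c-5p, let-7b-5p, let-7a-5p (-1.10), let-7f-5p (-1.07), let-7i-5p (-1.01) and miR-98-5p (-0.93). Both rises were the shared 3p pair. All 9 tested 5p arms had values below 0 under every scaling, though 2 rather than 6 passed with the library totals implied by RPM. The summed 5p arms took 15.6%, 26.2% and 11.99% of reads in the Sed libraries, the highest in Sed replicate 2, and 7.71%, 8.93% and 6.86% in the Exe libraries (means 17.9% ± 7.36 and 7.83% ± 1.04, SD).

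Of 21 tested brown fat promoting miRNAs, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.67. The rises were miR-26a-2-3p, miR-30c-1-3p, miR-455-3p (1.57), miR-193a-5p, miR-328-3p (1.26 ± 0.24) and miR-193b-3p (1.17 ± 0.29, adjusted p = 0.0167), which went from 3825 to 9351 reads. The fall was miR-32-5p (-1.35). Of the 21 values 14 lay above 0 and 7 below. Lower without a call were miR-193a-3p (-0.69) and miR-365-3p, from 2566 to 1315 reads, both picked after their values were seen. Several of the rises are minor arms, whereas the list's background concerns mostly the major ones. As a list it did not pass (camera adjusted p = 0.0807), and miR-193b-3p lost its call with library size alone (0.99) and without Sed replicate 3 (1.21), Exe replicate 1 (1.15) or Exe replicate 3 (1.33). Among 17 brown fat restraining miRNAs, 2 fell (2 adjusted over the list alone), miR-34a-5p (-1.05 ± 0.20), which restrains beige fat formation, and let-7i-5p, and none rose, with miR-27b-5p at 0.91 and miR-93-5p at 0.55.

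**Figure D2:**
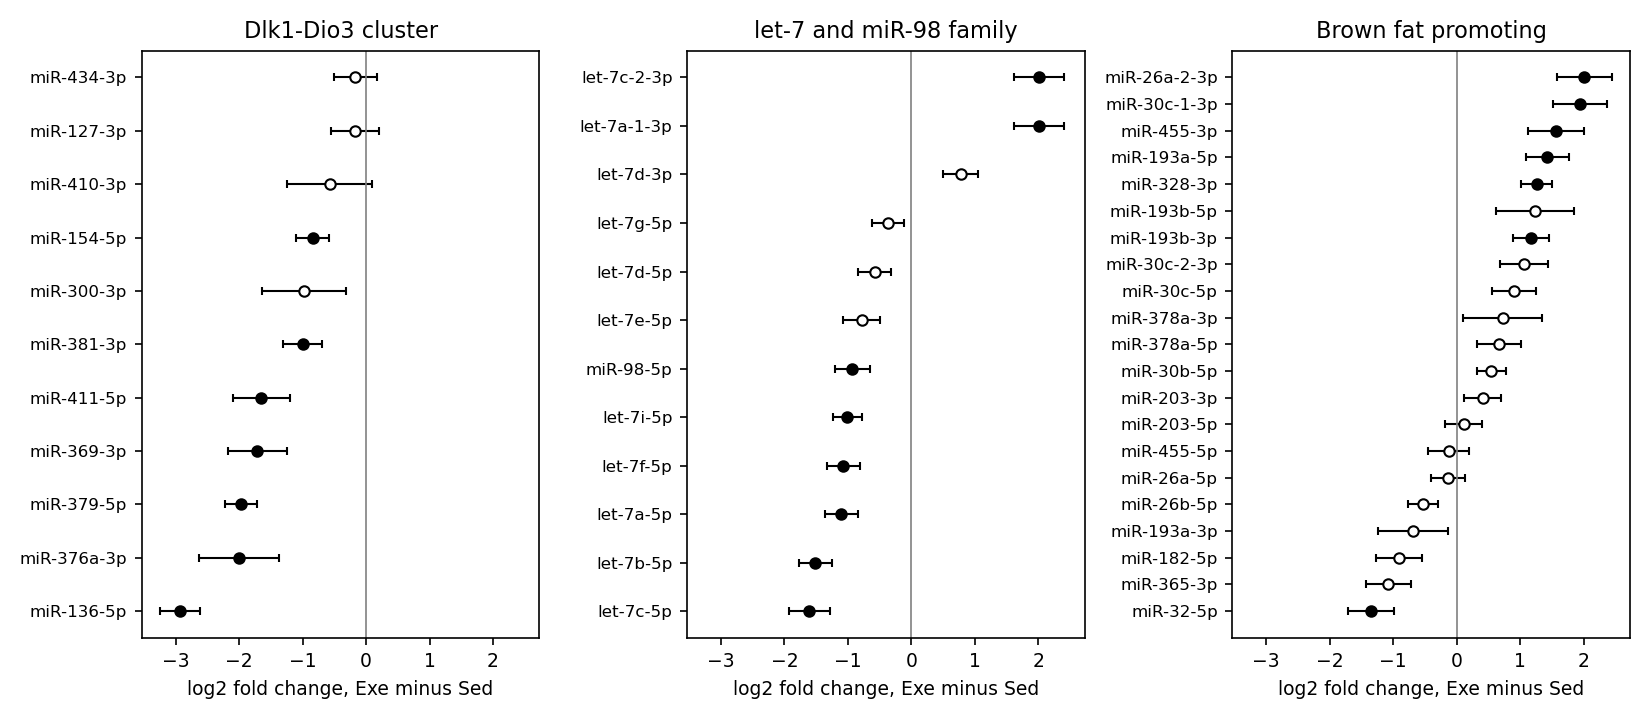
Log2 fold changes (Exe minus Sed, 3 libraries each) with SE bars of the tested members of 3 lists in BAT vesicles, filled where the adjusted p passed the threshold. The 11 Dlk1-Dio3 values lie below 0 at the main scaling (1 above with upper-quartile factors, 2 with totals implied by RPM), and the 3p arms of let-7 lie opposite its 5p arms.

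Lists of other cell sources showed single changes in BAT vesicles. For muscle, 2 of 6 fell (2 adjusted over the list alone), miR-1a-3p and miR-1b-5p, while miR-133a-3p was at 0.46 (adjusted p = 0.179) and miR-133b-3p at 0.71 (adjusted p = 0.175). For liver, 1 of 3 rose (1 adjusted over the list alone): miR-122-5p, the main hepatocyte miRNA, had 13, 5 and 4 reads in Sed and 88, 30 and 12 in Exe (2.62 ± 0.82, adjusted p = 0.0493), overlapping groups that no longer passed without Exe replicate 1 (1.37), replicate 1 of Sed (3.16), replicate 2 of Sed (2.48) or replicate 3 of Sed (2.51). The liver miRNAs miR-192-5p and miR-194-5p were at 0.18 and 0.19. In the red cell list 1 of 6 fell (0 adjusted over the list alone), miR-486b-3p (-1.13), with miR-486a-3p at -0.63 and the miR-486a-5p and miR-486b-5p pair at -0.71. The blood leukocyte list had 1 fall in 7 (1 adjusted over the list alone), miR-142a-3p (-1.19), with miR-223-3p at 0.65, miR-155-5p at 0.95 and miR-146a-5p at -0.39. Of 8 endothelial and platelet miRNAs 1 fell (1 adjusted over the list alone), miR-24-1-5p, with miR-23a-3p at 0.73, miR-24-2-5p at -0.55 and miR-191-5p at 0.41. Of 5 epithelial miRNAs 1 fell (1 adjusted over the list alone), miR-96-5p, with miR-182-5p at -0.91, miR-183-5p at -0.75 and miR-203-3p at 0.41.

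Among 14 adipocyte miRNAs 2 fell (2 adjusted over the list alone), miR-148a-3p (-1.29), which rises in fat cell formation, and miR-30e-5p (-0.94), with miR-30a-5p at -0.70 and miR-107-5p at -0.87. Neither miR-148a-3p (-0.67) nor miR-30e-5p (-0.68) passed without Sed replicate 2, nor did they with any single Exe replicate left out. In the miR-30 family 1 of 9 rose and 1 fell (2 and 2 adjusted over the list alone), miR-30c-1-3p and miR-30e-5p, with miR-30c-2-3p at 1.06. In the miR-29 family, which represses collagen genes, 1 of 4 fell (1 rose and 1 fell adjusted over the list alone), miR-29b-3p (-1.19), with miR-29a-3p at 0.69 (adjusted p = 0.0613), miR-29c-3p at -0.23 and miR-29c-5p at 0.22. From the 18 exercise in blood miRNAs 1 fell (1 adjusted over the list alone), miR-1a-3p. In the adipose vesicle (7 tested), fibroblast and stromal (10), neural (3) and miR-17-92 (7) lists edgeR called 0, also adjusted over the list alone. The values were miR-99b-5p 0.48, miR-92a-3p -0.17 and miR-222-3p -0.09 for adipose vesicles, and miR-21a-5p -0.40, miR-214-5p -0.55 and the miR-199a-3p and miR-199b-3p pair -0.57 for fibroblasts. Neural miR-218-5p, miR-7a-5p and miR-338-3p were at -0.49, 0.38 and 0.28, and miR-20a-5p, miR-19b-3p and miR-17-5p of the miR-17-92 clusters at -0.84, -0.75 and -0.45. None of these lists passed with camera, and no direction is given for them.

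The study candidates, which the study followed up in heart cells after choosing them on these samples, had 0 of 3 calls in BAT vesicles, also adjusted over the list alone. In BAT vesicles miR-128-3p was at 0.88 ± 0.32 (adjusted p = 0.0711), from 154 to 288 CPM, miR-125b-5p at -0.19 ± 0.25 (adjusted p = 0.599) and miR-30d-5p at 0.08 ± 0.21 (adjusted p = 0.785). With upper-quartile factors miR-128-3p passed (1.03), and without Sed replicate 2 (1.07). Among the 10 most abundant miRNAs only let-7c-5p and let-7f-5p passed. The others were miR-378a-3p at 0.73 ± 0.62, miR-22-3p at 0.48, miR-126a-3p at -0.12, miR-143-3p at 0.03, miR-451a at 0.17, miR-26a-5p at -0.14, miR-16-5p at -0.39 and miR-99a-5p at -0.01. With 1 library left out, miR-378a-3p ranged from 0.31 to 1.30, miR-22-3p from 0.21 to 0.91, miR-16-5p from -0.50 to -0.20 and miR-125b-5p from -0.31 to -0.06, while the values of miR-126a-3p, miR-143-3p, miR-451a, miR-26a-5p, miR-99a-5p and miR-30d-5p crossed 0.

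The same question was asked of plasma vesicles, where the leading miRNAs differed between the groups by far larger amounts but without passing the test. The red cell miRNA miR-451a was at -3.03 ± 0.57 (SE, n = 2 per group, adjusted p = 0.0899), with 936594 and 948848 reads in Sed and 134144 and 232086 in Exe. Values above 0 were those of let-7c-5p (3.26 ± 0.55, adjusted p = 0.0899), let-7b-5p (3.03 ± 0.65), miR-25-3p (3.90 ± 0.79), miR-10b-5p (6.85 ± 1.49) and the islet and endocrine miRNA miR-375-3p (7.62 ± 1.12, adjusted p = 0.0841, the smallest). For miR-34a-5p the value was -3.63 ± 0.76. The other abundant miRNAs were let-7a-5p at 2.50, let-7g-5p at -0.82, let-7i-5p at 0.39, let-7f-5p at 0.49, miR-16-5p at -0.63 and miR-24-3p at -1.62. With 1 library left out, let-7g-5p ranged from -1.26 to -0.04, let-7i-5p from 0.40 to 0.92, let-7f-5p from 0.43 to 0.93 and miR-24-3p from -1.62 to -1.03, while miR-16-5p and miR-122-5p crossed 0. In Exe plasma miR-203b-5p, miR-203-5p and miR-193b-3p were at 0 reads, at least 10.7-fold, 19.1-fold and 23.3-fold lower than in Sed. These bounds, and the bounds and counting intervals given below for plasma, cover counting error only and not the spread between replicates.

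In plasma edgeR's quasi-likelihood test called 0 of 182 miRNAs, with 60 at an unadjusted p under 0.05, while DESeq2 called 59 and limma-voom 35. Without Sed replicate 1, Sed replicate 2, Exe replicate 1 or Exe replicate 2 it called 27, 24, 27 and 3, with the lone library of that group assumed to vary like the others. Upper-quartile factors moved the median by -0.91, library size alone by 0.62 and DESeq2 by -0.16. In simulated data with the spread of these libraries, 0.769% of 8-fold changes were recovered.

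**Figure D3:**
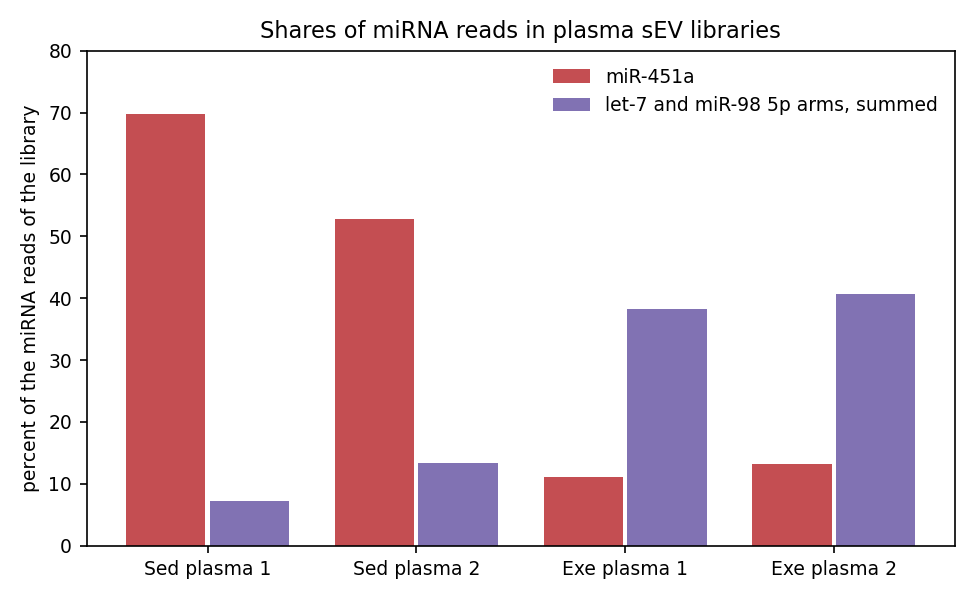
Percent of miRNA reads taken by miR-451a and by the summed let-7 and miR-98 5p arms in each of the 2 Sed and 2 Exe plasma vesicle libraries. The miR-451a bars stand at 69.8% and 52.8% in Sed and near 11.1% and 13.1% in Exe, and the let-7 bars at 7.30% and 13.4% in Sed and 38.2% and 40.7% in Exe. A lower share of miR-451a raises every other share, so the let-7 bars alone do not measure a rise of let-7. The median log2 fold change of the 9 tested 5p arms was 0.67 at the main scaling and -0.23 with upper-quartile factors.

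No list passed in plasma with camera, with an estimated correlation or with fry for a change in one direction, while 13 passed fry for changes in mixed directions. With camera 1 list passed without Exe replicate 1 and 1 without Exe replicate 2. In the let-7 and miR-98 family 0 of 10 passed (4 rose adjusted over the list alone), with a median of 1.27 that stayed above 0 under each scaling, while with upper-quartile factors 5 of the 10 lay below 0, and let-7d-3p was at 4.35 ± 1.37. The median of the 9 tested 5p arms was 0.67, but with upper-quartile factors it was -0.23, with 4 above 0 and 5 below. Of 11 epithelial miRNAs 0 passed (1 rose and 6 fell adjusted over the list alone), among them miR-205-5p, at least 238-fold lower in Exe, and miR-200c-3p at -6.548 ± 2.001, and the list's median was -4.25 with miRNAs at 0 reads set to their bound. Of 8 neural miRNAs 0 passed (1 rose and 4 fell adjusted over the list alone), with miR-124-3p at least 215-fold lower, miR-338-5p at least 35.8-fold lower, miR-9-5p at -7.44, miR-7a-1-3p at a ratio of 886 (95% counting interval 245 to 7320, higher in Exe) and a median of -2.86 set the same way. Of 4 liver miRNAs 0 passed (1 fell adjusted over the list alone): miR-122-3p was at least 533-fold lower, but miR-122-5p, the abundant arm, was at -0.58 ± 0.61, miR-194-5p at -6.40 and miR-192-5p at -0.05. Of 6 red cell miRNAs 0 passed (2 rose and 1 fell adjusted over the list alone), with miR-486b-3p at 6.83 ± 1.88 and miR-486a-3p, at 0 reads in Sed, at least 270-fold higher, opposite in sign to miR-451a, and miR-486a-5p at 2.72. On the side of miR-451a was miR-144-3p, chosen after its values were seen (-1.57 ± 1.91, from 29 to 10 reads).

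Among 5 blood leukocyte miRNAs 0 passed, also over the list alone, with miR-150-5p at 2.99 ± 1.04 and miR-342-3p at 6.85 ± 2.53, miR-223-5p at 6.21 and miR-223-3p at 1.60. The 12 brown fat promoting and 11 brown fat restraining miRNAs had 0 calls (2 falls each adjusted over the list alone), with miR-30b-5p at -5.51, miR-27b-3p at -3.15, the miR-199a-3p and miR-199b-3p pair at -2.12 and miR-196a-5p at least 118-fold lower. For the adipocyte list (10 tested) and the miR-17-92 clusters (5) edgeR called 0, with 1 rise each adjusted over the list alone, and miR-92a-3p was at 2.08, miR-19b-3p at -1.02, miR-30e-5p at -8.38 and miR-22-3p at -1.21. Lower in Exe by a ratio of 99.7 (27.1 to 832) was miR-20a-5p, and by 13.5 (4.18 to 69.2) miR-22-5p. The adipose vesicle (7), muscle (4), endothelial and platelet (7), fibroblast and stromal (6), miR-30 (6), miR-29 (3), Dlk1-Dio3 (11) and exercise in blood (17) lists had 0 calls, also over the list alone. In these, miR-191-3p was at least 221-fold higher and miR-376a-3p at least 25.1-fold lower in Exe, and miR-433-3p was lower by a ratio of 44.6 (11.9 to 377), with miR-341-3p at 6.47 and miR-127-3p at 2.94. Muscle miRNAs were miR-206-3p at 6.07, miR-499-5p at -0.86, miR-133a-3p at 1.23 and miR-1a-3p at -0.21, and adipose ones miR-99b-5p at -1.99, miR-221-3p at -4.82 and miR-99a-5p at -1.45. For miR-23a-3p the value was 2.37, for miR-126a-3p -1.0, for miR-199a-5p 2.93, for miR-145a-5p 3.01, for miR-30a-3p 3.53 and for miR-378a-3p -2.90. In the miR-29 family, miR-29b-3p was at -6.45, miR-29c-3p at -2.93 and miR-29a-3p at -0.66.

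The study candidates had 0 of 3 calls in plasma, also over the list alone, with miR-30d-5p at 3.88 ± 1.48 (adjusted p = 0.128), miR-128-3p at 4.36 ± 1.76 (adjusted p = 0.146) and miR-125b-5p at 2.02 ± 1.74 (adjusted p = 0.464). Without Sed replicate 1, miR-30d-5p was at 5.24 (adjusted p = 0.00369), and without Sed replicate 2 miR-128-3p was at 6.94 (adjusted p = 0.0169). With DESeq2 both passed (3.78 and 4.16), and miR-125b-5p was between 0.92 and 3.33 with 1 library left out. As the study chose them on these samples, their common sign in plasma is not independent evidence.

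Whether exercise acted differently on the miRNAs of the vesicle sources was tested as a difference of effects. For let-7b-5p and let-7c-5p the effect in BAT lay below that in plasma by 4.26 and 4.37 on the log2 scale (-4.26 ± 0.62 and -4.37 ± 0.72, SE, adjusted p = 0.00264 each), from 9800 to 3609 reads of let-7b-5p over the BAT libraries and from 8794 to 109879 over the plasma libraries. The difference was -6.06 for miR-10b-5p and -7.50 for miR-486b-3p. Opposite differences were those of miR-27b-3p (4.02 ± 0.64) and miR-31-5p (8.08 ± 1.28). For miR-193b-3p, miR-486a-3p and miR-122-3p, each with a group at 0 reads, and for the epithelial miR-203-3p, with 365 reads in Sed and 2 in Exe plasma, the adjusted p was 0.00264 and no size is given.

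Of 234 miRNAs in the joint fit, 68 differed in their exercise effect, 39 with the higher effect in BAT and 29 with the higher effect in plasma. Second values were 30.2% and 4.67% of reads in Sed plasma and 71.0% and 61.1% in Exe plasma. This percent counts miR-451a, which held 69.8% of reads but 30.2% of second values in Sed plasma replicate 1. The gap between the plasma groups therefore rests in part on miR-451a. In Sed plasma replicate 2 miR-451a held 52.8% of reads and 38.9% of second values. The 4.67% of that library is thus not made by miR-451a alone. A single library cannot show that library make-up differed between the plasma groups for other miRNAs. A part of library make-up in the plasma effects is not excluded. The joint fit gives both sources 1 spread, and limma-voom with a spread for each source, chosen after seeing the data, called 25, all of them among the 68. In simulated data with the spread of each source, 60% of the calls of the joint fit and 42.9% of those with a spread for each source were false. These shares rest on few simulated calls, with means of 2.25 and 0.3 false calls per run. They are no estimate of the false share among the 68 or the 25, but single calls are uncertain. Upper-quartile factors moved the median by 1.05 and gave 63 and 20, and library size alone moved it by -1.04 and gave 27 and 51. DESeq2, which changes the test as well, moved it by 0.41 and gave 59 and 43. The count was 36, 37, 37, 38 and 40 without Sed BAT replicates 1 and 3 and Exe BAT replicates 1, 2 and 3, and 119 without Exe plasma replicate 1.

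Across the 136 miRNAs tested in both sources, the fitted exercise effects showed little correlation. Plasma replicates correlated at only 0.747 in Sed and 0.806 in Exe (Pearson, log2 CPM). A low correlation can arise from that spread alone, so it cannot show that the effects are unrelated. Pearson's r was 0.103 and Spearman's rho 0.0912, across miRNAs, which are not independent replicates, and 68 miRNAs (50%) had the same sign in both. Of 30 splits of the libraries within both sources, 15 gave a correlation as far from 0. Without miRNAs at 0 reads in a plasma group r was 0.172 over 131, and it was 0.256 without Sed plasma replicate 1, 0.304 without Sed plasma replicate 2, 0.169 without Exe plasma replicate 1, 0.194 without Exe plasma replicate 2, 0.156 without Sed BAT replicate 2, and 0.0433 and 0.0592 without Sed BAT replicate 3 and Exe BAT replicate 1.

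**Figure D4:**
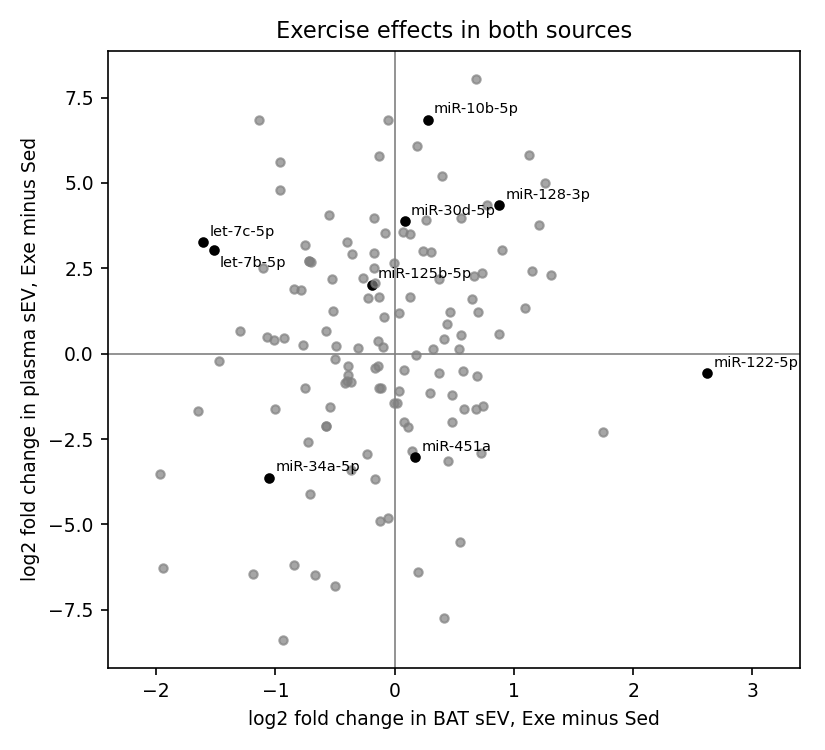
Log2 fold changes (Exe minus Sed) in BAT vesicles against those in plasma vesicles for the 131 miRNAs tested in both with reads in every group, each point a miRNA. The let-7b-5p and let-7c-5p points lie below 0 in BAT and above 0 in plasma, and the axes differ in scale.

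The last comparison asked what set BAT vesicles apart from plasma vesicles without training. Higher in plasma was the liver miRNA miR-122-5p, with 22 reads over the Sed BAT libraries and 135963 over the Sed plasma libraries (-12.16 ± 1.21, SE, 3 against 2 libraries). Likewise miR-122-3p was at least 289-fold higher in plasma, and miR-215-5p had a ratio of 10644 (95% counting interval 1910 to 420449, from 1 BAT read). The red cell miRNA miR-451a (-6.39 ± 0.49), miR-25-3p (-5.60), the epithelial miR-200c-3p (-6.50) and miR-429-3p (-5.77) and the neural miR-9-5p (-6.16) and miR-9b-3p (-5.68) were also higher in plasma. Higher in BAT were miR-193a-3p, a miRNA of brown fat formation, with a ratio of 2114 (379 to 83549, from 1 plasma read), the muscle miRNAs miR-1b-5p, with a ratio of 864 (155 to 34172), and miR-133a-3p (7.64 ± 2.32), and, at least 102-fold, 61.3-fold and 36.6-fold, miR-32-5p, miR-146b-5p and miR-486a-3p. The miRNAs miR-214-5p, miR-199b-5p, miR-339-5p and miR-326-3p were at least 35.3-fold, 32.2-fold, 31.3-fold and 16.3-fold higher in BAT. The muscle list as a whole was mixed in the Sed libraries. In the joint fit miR-206-3p had a mean of 4065 CPM in BAT and 30.9 in plasma. Against that, miR-1a-3p had 9697 in BAT and 11582 in plasma, and miR-499-5p 427 and 3007.

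Of 234 miRNAs, 52 were higher in BAT and 47 in plasma, 99 in all. The split depended on the method. Library size alone, which moved the median by 2.62, gave 138 and 14, upper-quartile factors, which moved it by 0.20, gave 58 and 47, and DESeq2, which changes the test as well as the scaling and moved it by 0.44, gave 101 and 49. In simulated data with the spread of each source, 50.8% of the calls of this fit were false. That share rests on a mean of 3.2 false calls per run and is no estimate for the 99, but single calls are uncertain. In Sed plasma replicates 1 and 2, miR-350-3p (-6.02 ± 1.94) had 0 and 3676 reads, miR-215-5p 3 and 14078 and miR-133a-3p 28 and 0, so that each value depends on which library is read. Without Sed plasma replicate 2, miR-215-5p and miR-133a-3p no longer passed, miR-350-3p passed with the opposite sign, and miR-9b-3p went to -3.47. The call of miR-350-3p was also lost without Sed BAT replicates 1, 2 or 3. With the Exe libraries, miR-200c-3p (-0.49), miR-146b-5p (2.84) and miR-214-5p (2.21) no longer passed, and miR-486a-3p (-2.78), miR-9-5p (1.94) and miR-9b-3p (2.89) turned.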

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

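The tests of the let-7 3p arms, of the other red cell miRNAs, of the second plasma values, of the library make-up and of the plasma read totals, and the fit with a spread for each source, were chosen only after the result they bear on was seen.

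The exercise effect differed between BAT and plasma vesicles, by the test of the difference itself, for 68 of 234 miRNAs. The 10 of smallest p were let-7b-5p (-4.26), let-7c-5p (-4.37), miR-10b-5p (-6.06), miR-486b-3p (-7.50), miR-27b-3p (4.02) and miR-31-5p (8.08), as BAT minus plasma effect in log2 units, then miR-193b-3p, miR-486a-3p and miR-122-3p, with a group at 0 reads, and miR-203-3p, with 2 reads in Exe plasma, with an adjusted p of 0.00264 each. With limma-voom and a spread for each source the count was 25. In simulated data with such spread 60% of the calls of the joint fit were false. That share rests on a mean of 2.25 false calls per run and is no estimate for the 68, but single calls are uncertain. The percent of reads in the second values did not overlap between the plasma groups. That percent counts miR-451a, which held 69.8% of reads but 30.2% of second values in Sed plasma replicate 1. The gap between the groups therefore rests in part on miR-451a. In Sed plasma replicate 2, at 4.67%, miR-451a held 52.8% of reads and 38.9% of second values. That low percent is thus not made by miR-451a alone. A single library cannot decide whether library make-up differed between the groups for let-7 or other miRNAs. For the plasma part of every difference, let-7 included, library make-up stays open.

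The let-7 and miR-98 5p arms were lower in Exe BAT vesicles, with a median log2 fold change of -1.01 over 9 miRNAs. The tables argue against Sed replicate 2 as the whole cause, since the median was -0.86 without that library (median SE 0.25). Without the 3 most abundant miRNAs it was -0.99 (median SE 0.26). That value cannot decide on a composition effect of abundant miRNAs, since TMM scaling already trims extreme miRNAs with or without them. Over the scalings the median ranged from -1.15 (library size alone) to -0.81 (library totals implied by RPM). The tables also argue against less let-7 precursor of every kind: the 3p arms of let-7a-1 or let-7c-2 and of let-7d had a median of 1.39 (largest SE 0.39), although these rest on few reads and cover only those precursors. An effect of exercise on the loading or stability of let-7 5p arms may remain, as an untested hypothesis.

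In plasma miR-451a was at -3.03 in Exe, and its log2 ratio to miR-23a-3p, a common sign of red cell RNA, was 9.91 and 6.43 in Sed against 1.88 and 2.80 in Exe. Much of that fall came from miR-23a-3p, with 975 and 11005 reads in Sed and 36508 and 33325 in Exe, so the ratio is no clear sign of red cell RNA here. Less red cell RNA cannot be told apart from other causes: by the most abundant entry of each, the other red cell miRNAs had a median of 0.57, miR-486a-5p at 2.72 against miR-451a and miR-144-3p at -1.57 with it (29 and 10 reads). Reads left out of the second plasma values do not make up the whole fall, since miR-451a was at -2.15 ± 0.28 there. The second values were 30.2% and 4.67% of reads in Sed and 71.0% and 61.1% in Exe. The lowest Exe percent was thus 2.02 times the highest Sed percent. However, miR-451a held 69.8% of reads and 30.2% of second values in Sed replicate 1, so its own level enters this percent. The percent therefore cannot decide whether library make-up explains the fall. Library make-up and exercise both stay open, untested.

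Plasma replicates disagreed on which miRNAs were present. Of miRNAs with over 100 reads in 1 library, 21.7% in Sed and 40.4% in Exe had at most 20 in the other, against at most 1.08% between BAT replicates. These cut-offs are raw reads. As the plasma libraries were deeper, the cut-offs take in rarer miRNAs in plasma than in BAT, so the sources are not compared at like abundance. Too few reads are argued against, since the shallowest plasma library had 7.02 times the miRNA reads of the deepest BAT library. Few molecules of each miRNA having entered the plasma libraries could give such values, but a contrast with BAT at unlike abundance cannot show it. It stays untested, as the labels do not say whether the second plasma values count molecules. No biological explanation was tested.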

How the results depend on the processing

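The library totals implied by RPM, identical miRNAs counted once, the second plasma values and the spread for each source were chosen after seeing the data. The cause of the changes below was not tested, except where fewer miRNAs or libraries entered.

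For BAT vesicles the 45 calls became 40 with DESeq2, 41 with limma-voom and 43 with identical miRNAs once, and 21 with a mean of at least 50 counts, where 107 instead of 199 were tested. Leaving out 1 library gave 16 to 56. In plasma the 0 calls of edgeR became 59 with DESeq2, 35 with limma-voom, 4 with upper-quartile factors, 10 with library size alone, 17 with no filter, 29 with a mean of at least 50 counts, 1 without the 3 most abundant miRNAs, 11 with the second plasma values and 3 to 27 with 1 library left out. The 68 differences of effects became 25 with a spread for each source, and 36 to 119 with 1 library left out. BAT against plasma went from 99 to 150 with DESeq2, 152 with library size alone and 156 with the Exe in place of the Sed libraries. In BAT 0 lists passed with an estimated correlation and 0 with fry in one direction, and 1 to 3 with 1 library left out. In plasma 0 to 1 passed so. The correlation of effects ranged from 0.0433 to 0.304 with 1 library left out.

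Signs turned in BAT for 6 miRNAs near 0, none past the threshold. With upper-quartile factors these were miR-126a-3p (0.021), miR-26a-5p (0.027) and miR-99a-5p (0.145), with the totals implied by RPM the same miRNAs (0.151, 0.037 and 0.225), and with a mean of at least 50 counts again these (0.0074, 0.0122 and 0.133). For miR-99a-5p the sign also turned with DESeq2 (0.0144), no filter (0.000815) and without the 3 most abundant miRNAs (0.0208). Library size alone turned miR-30d-5p (-0.045) and miR-143-3p (-0.016). With 1 library left out, miR-30d-5p ranged from -0.00492 to 0.228, miR-126a-3p from -0.254 to 0.152, miR-143-3p from -0.229 to 0.459, miR-451a from -0.182 to 0.608, miR-26a-5p from -0.191 to 0.0557 and miR-99a-5p from -0.0234 to 0.113. In plasma signs turned for let-7i-5p (-0.58) and let-7f-5p (-0.48) with upper-quartile factors. With 1 library left out, miR-122-5p ranged from -0.95 to 0.11 and miR-16-5p from -0.98 to 0.065 in plasma, and miR-350-3p from -6.97 to 7.64 between BAT and plasma, the latter fitted against 0 plasma reads and no estimate of size. With the Exe libraries, the difference of BAT from plasma turned for miR-486a-3p (-2.78), miR-9-5p (1.94), miR-9b-3p (2.89) and miR-122-3p (a fitted 4.27, with 4 reads in BAT and 0 in plasma, no estimate of size). Over the other values of named miRNAs, 603 in BAT, 176 in plasma, 179 for differences of effects and 254 between sources kept their direction and their side of the threshold, and 154, 0, 1 and 14 kept the direction but lost the call. In BAT 2 values and in plasma 84 gained one.

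Equal replicate numbers did not pair the libraries: the deviations of same-numbered BAT libraries correlated at 0.00425, -0.0833 and -0.12, those of plasma at -0.0755, and no library matched its own number best. With the number as a block, 25 BAT miRNAs and 7 plasma miRNAs were called, 1 BAT list and 0 plasma lists passed, and the correlation of effects was 0.112.

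Depth limited the BAT vesicles: 3 counts amount to 17.4 to 28.8 CPM in a BAT library, against 1.67 to 2.48 in a plasma library.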

Other observations

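The test of other splits for single miRNAs was chosen only after the result was seen, and the tests of arms, of neighbouring genes and of splits for lists before.

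In BAT vesicles, several precursors had arms at opposite values, and the arms named here were chosen after their values were seen. For miR-142a, of blood cells, the 3p arm was at -1.19 and the 5p arm at 0.62, for miR-193a the 3p arm at -0.69 and the 5p arm at 1.43, and for miR-455 the 3p arm at 1.57 and the 5p arm at -0.12. Such a shift of minor against major arms may be part of the response to exercise. Over 33 pairs of tested arms, however, the median difference (minor minus major arm) was 0.157, the minor arm was higher in 19, and the sign permutation p was 0.178. That p treats the pairs as independent. Some share an arm (miR-24-3p or miR-30c-5p) or its reads (miR-199a-3p with miR-199b-3p, and miR-486a-5p with miR-486b-5p). A general rise of low-abundance miRNAs was not shown either: Spearman's rho of log2 fold change with mean reads was -0.0862 over 199 miRNAs. Both explanations stay open.

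The miRNA genes miR-182, miR-183 and miR-96 lie within 10 kb of each other in GRCm38, and their 5p arms were at -0.91, -0.75 and -1.94, of which only miR-96-5p passed. If neighbouring genes share a transcript, their vesicle miRNAs might move together. The mean absolute difference of log2 fold changes was 1.02 for 36 neighbouring pairs outside the Dlk1-Dio3 cluster, against 1.01 for random pairs (permutation p = 0.527), and 1.02 against 1.01 for all 46 pairs (p = 0.517). Only miRNAs with exactly 1 gene of their name entered. Some pairs use the shared let-7a-1-3p and let-7c-2-3p reads, which cannot be assigned to a gene. Their 2.01 was set against let-7d-3p (0.78), let-7d-5p (-0.58) and let-7b-5p (-1.52), which can raise the mean. Within the Dlk1-Dio3 cluster, miR-136-5p (-2.93) lies within 10 kb of miR-127-3p (-0.18) and miR-434-3p (-0.17), which did not pass and were chosen after their values were seen. Of all 46 pairs 30 had the same sign, against 20 of the 36 outside the cluster. Outside the cluster no shared movement was detected, and it is not excluded.

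The 6 BAT libraries make 10 splits, too few for a share under 0.05. The real split gave 45 miRNAs, and it was the 1 split with as many, the highest of the others giving 1. For lists the real split gave 1, the highest other split gave 3, and 6 of the 10 gave as many.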
